A study of Danio rerio with 2 samples.

How the data were processed

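Small RNA libraries were made from whole zebrafish (Danio rerio) embryos at 14 hours post fertilisation. Per the labels' protocols, 1 nl of morpholino solution was injected into each embryo at the 1-cell stage. Morpholinos (MOs) are antisense oligomers that block translation or splicing of a chosen transcript. The knockdown embryos received 6.25 ng of gata5 MO together with 1.25 ng of gata6 MO, and the control embryos received 7.5 ng of control MO. Total RNA came from 80 embryos per library, small RNA was purified with a column kit, adaptors were ligated to both ends, and a gel slice was taken after PCR. The label of the control sample reads wild type although the protocol describes a control MO, and the label of the other sample names gata4 beside gata5 and gata6 although no gata4 MO is described. The groups are called control and gata5/6 here, each with 1 library.

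For each library the authors deposited a table of distinct small RNA sequences of 15 to 36 bases with the raw count of reads of each, per the file headers and the values. A further deposited table for the whole series lists 8 microRNAs with the authors' log2 fold change, p-value, FDR and read counts. The trimming tool, aligner, genome build, microRNA annotation and test behind these tables were not given in the sources used here. The authors' log2 values equal the log2 ratio of their 2 counts plus 0.14 for each of the 8 microRNAs, which is close to the 0.145 that scaling by microRNA reads gave here and differs from the -0.02 of scaling by all reads. Their ratios of FDR to p-value give whole ranks, within a tolerance of 1e-06, for 365 tests, the smallest such number found. With that number the 8 microRNAs hold ranks from 9 to 130, so other microRNAs with smaller p-values were left out of the table, and the smallest absolute log2 fold change in it is 1.00.

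No genome or mature microRNA annotation was used here. A list of 163 mature sequences was written from general knowledge after the files had been opened, and every microRNA name therefore rests on the sequence assigned to it. The sequence of miR-125c was corrected after comparison with the authors' table, so its match to that table is not independent. The forms of miR-430a and miR-430b and the first base of miR-31 were settled on the abundant reads that fitted them. Near-identical pairs such as miR-133a and miR-133b, miR-16a and miR-16b, miR-141 and miR-200a, or miR-200b and miR-200c differ by few bases near the 3′ end, where trimming and tailing occur, and their separate values are uncertain. MicroRNAs outside the list were not counted. Gene neighbours were looked up by name in the RefSeq gene table of the GRCz12tu assembly, where 154 of 156 microRNA names had an entry, and no coordinates were used because the authors' build is not given in the sources used here.

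A read was assigned to a microRNA if it was at least 18 bases long, began within 2 bases of the mature 5′ end, extended at most 3 bases past the mature 3′ end, and equalled the mature sequence except in its last 2 bases. The name with the fewest differences was taken, and reads tied between names were left out, which removed 455 reads from the control and 355 from the gata5/6 library. Counts were scaled to the total of assigned microRNA reads. The log2 ratio of gata5/6 to control used a pseudocount of 0.5 reads, and each ratio has an exact conditional (Clopper-Pearson) 95% interval.

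With 1 library per group no test between conditions was possible, and no p-value was computed. A microRNA was counted as higher or lower when the libraries differed at least 2-fold, the interval excluded 1 and both libraries together held at least 100 reads. Intervals, and the floor of 3 counts (0.522 CPM of microRNA reads in the control and 0.577 CPM in the gata5/6 library), cover counting error only. Intervals treat reads as independent, whereas PCR reads without molecular identifiers are not independent molecules, so they may be too narrow even for that error. They say nothing of the spread between batches of embryos.

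Before the data were examined, 14 lists of microRNAs were fixed, for heart and skeletal muscle, smooth muscle, endothelium, blood, liver, pancreas and gut, mesenchyme, the nervous system, sensory organs, skin and epithelium, Hox clusters, miR-430, miR-17 to miR-92, let-7 with miR-98, miR-99, miR-100 and miR-125, and p53-responsive microRNAs. The lists overlap in miR-143 (smooth muscle and mesenchyme) and in miR-192 and miR-194a (liver, pancreas and gut, and p53-responsive). Members with at least 20 reads entered with their more abundant arm. The median log2 ratio of a list was placed among 10000 random lists of equal size, each member drawn from the 20 microRNAs nearest in abundance. For the most abundant members, as in the miR-430 and Hox-cluster lists, the nearest ones include far less abundant microRNAs, so the match is loose there. The percentile describes these libraries and is not a test between conditions. Also fixed beforehand was which microRNAs are named: those in the authors' table, the 10 most abundant, up to 10 of the largest differences in each direction among those counted, and the 4 most abundant members of each list. Any others that appear were chosen after their values were seen.

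Other small RNAs were counted by sequence: 5′ fragments of 4 tRNAs from sequences of general knowledge (a further fragment is not reported here), reads of 26 to 30 bases outside the microRNAs, and 5 conserved motifs of bacterial 16S ribosomal RNA. These were scaled to all reads.

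Alternatives were edgeR's TMM factors (4.0.16), DESeq2's median-of-ratios factors (1.42.0), the total of all reads, the total without miR-430, no minimum or a minimum of 20 reads, reads that equal the mature sequence only, ambiguous reads split, a pseudocount of 1, and 1.5-fold or 4-fold limits. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and R 4.3.3, and plots matplotlib 3.10.9.

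The counting rule was tested on simulated data made from 104 microRNAs at the depths of these libraries, in 20 simulations with 40 changed microRNAs each. It counted 94.6% of 3-fold changes, 94.2% of 4-fold changes, 1.07% of 1.5-fold changes and 0 of the unchanged microRNAs, and 95.1% of intervals held the true ratio. The simulation held counting error only, with no spread between pools of embryos or preparations, so it does not show how often the rule would count a difference between 2 replicate libraries. Of 3240 simulated reads 0 were assigned to another microRNA and 90 were left ambiguous, and 0 of 20000 random sequences were assigned. The simulated reads were listed sequences with shortened ends, without sequencing errors, added bases or RNAs outside the list. They barely test confusion between near-identical microRNAs.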

Results

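Small RNAs of 14-hour zebrafish embryos were sequenced to ask how microRNA levels differ after injection of MOs against gata5 and gata6, which encode zinc-finger transcription factors of heart and endoderm development. There was 1 library per group, each from 80 pooled embryos. The control library held 9828279 reads of 1525820 distinct sequences, and the gata5/6 library held 9950517 reads of 1695146 distinct sequences. Listed microRNAs took 5747354 control reads and 5197762 gata5/6 reads, and 161 of the 163 listed sequences had reads. The mRNAs of gata5 and gata6 are not measured in such libraries, so the knockdown itself was not checked. No replicate check of any difference was possible, and all intervals are 95% intervals of counting error.

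Few microRNAs differed 2-fold between the libraries. Higher in the gata5/6 library were miR-7b (TGGAAGACTTGTGATTTTGTTGTT), a microRNA of neural and endocrine cells, by 2.91-fold, and miR-210-5p (AGCCACTGACTAACGCACATTG), from the hypoxia-inducible miR-210 hairpin, by 2.71-fold. Lower were miR-722 (TTTTTTGCAGAAACGTTTCAGATT), by 3.43-fold, and the sequence listed as miR-738 (GCTACGGCCCGCGTCGGGA), by 5.17-fold. Neither is counted as lower when only reads equal to the listed sequence are used. Of these miR-722 had 0 and miR-738 had 2, too few to judge either call. The other 103 of the 107 microRNAs with at least 100 reads lay within 2-fold, and 88 of the 107 had an absolute log2 ratio under 0.5. The reads behind the differences were 117 in the control and 308 in the gata5/6 library for miR-7b (log2 ratio 1.54, interval 1.23 to 1.86) and 244 and 599 for miR-210-5p (1.44, 1.22 to 1.66). They were 269 and 71 for miR-722 (-1.77, -2.18 to -1.39) and 223 and 39 for miR-738 (-2.36, -2.90 to -1.87). Most miR-722 reads did not begin at the listed 5′ base, and only 10.8% of control and 7.04% of gata5/6 reads did. Of the 1221 reads of any length that contained the core of the miR-738 sequence, 1.72% began at its mature 5′ end. By that measure 51.5% of 66 miR-722 reads did, a count that leaves out reads lacking the first bases of the core. In the annotation, the miR-722 gene lies in gcgrb, miR-210 between rassf7a and phrf1, and miR-7b in hnrpkl and an overlapping locus.

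**Figure D1:**
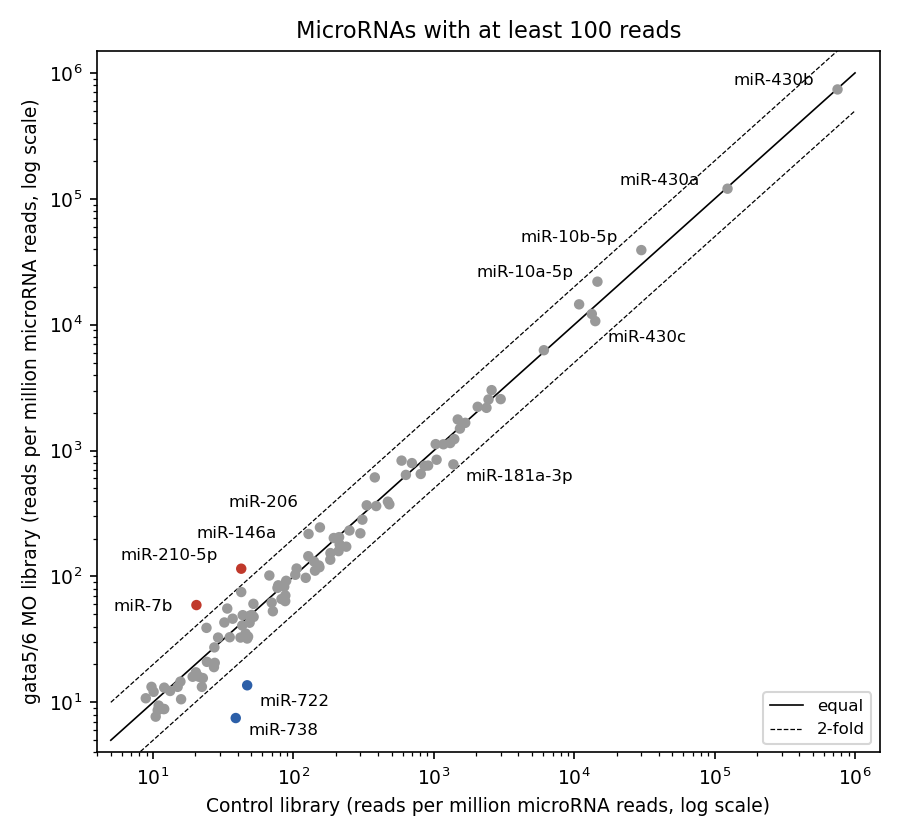
Levels (CPM of microRNA reads) of the 107 microRNAs with at least 100 reads, in the control library (x axis, log scale) and the gata5/6 MO library (y axis, log scale). Each point is 1 microRNA, the solid line marks equal levels and the dashed lines a 2-fold difference; the 2 red points (miR-7b, miR-210-5p) lie above and the 2 blue points (miR-722, miR-738) below these lines.

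The 8 microRNAs of the authors' deposited table pointed the same way in the reads counted here, but miR-129-5p did so only under some scalings and by a small amount. Beyond the 4 above, miR-30a (TGTAAACATTCCCGACTGGAAG) and miR-125c (TCCCTGAGACCCTAACTCGTGA) were higher in the gata5/6 library, and miR-153a (TTGCATAGTCACAAAAGTGATC), a microRNA of neurons, was lower. Each of these 3 had under 100 reads. From 17 control and 37 gata5/6 reads miR-30a had a log2 ratio of 1.24 (0.40 to 2.19), where the authors' deposited table gives 1.41, but only 0 control and 2 gata5/6 reads equalled the listed sequence. From 35 and 64 reads miR-125c had 1.01 (0.40 to 1.65), against 1.00 in the authors' deposited table, a match that is not independent because its sequence was corrected with that table at hand. From 48 and 16 reads miR-153a had -1.41 (-2.36 to -0.60), against -1.27 in the authors' deposited table. For miR-7b, miR-210-5p, miR-722 and miR-738 the authors' deposited table gives 1.54, 1.46, -1.54 and -2.38. It was miR-129-5p (CTTTTTGCGGTCTGGGCTTGC) that stood apart, with 18 control and 17 gata5/6 reads and a log2 ratio of 0.06 (-0.98 to 1.10), turning negative with scaling by all reads or without miR-430. For it the authors' deposited table gives 19 and 44 reads and a log2 value of 1.35. So 7 of the 8 were at least 2-fold apart here in the authors' direction with an interval excluding 1. With scaling by all reads or without miR-430 there were 6, since miR-125c had log2 ratios of 0.84 and 0.79, and with exact sequences there were 3.

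The most abundant microRNA family was miR-430, which clears maternal mRNAs in the early embryo, and its share was similar in both libraries. It took 88.8% of control microRNA reads (88.80% to 88.85%, Clopper-Pearson) and 87.0% of gata5/6 microRNA reads (86.99% to 87.04%). With 75.1% and 73.9% of microRNA reads, miR-430b (AAAGTGCTATCAAGTTGGGGTAG) had a log2 ratio of -0.02, and miR-430a (TAAGTGCTATTTGTTGGGGTAG) of -0.04; both turn positive with TMM or median-of-ratios scaling. The less abundant miR-430c (TAAGTGCTTCTCTTTGGGGTAG) was lower in the gata5/6 library, at 14119 and 10671 CPM of microRNA reads and a log2 ratio of -0.40 (-0.42 to -0.39). The median of the 3 family members was -0.04, and no percentile is given because no other microRNA comes near miR-430b in abundance. Among the other abundant microRNAs, miR-92a had -0.13 (-0.15 to -0.12), miR-203b of the skin -0.22 (-0.26 to -0.19) and miR-92b 0.23 (0.20 to 0.26). For miR-21 the value was 0.04 (0.02 to 0.07), which turns negative with scaling by all reads or without miR-430.

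MicroRNAs of the Hox clusters, mostly the miR-10 group, were higher in the gata5/6 library. Of the 6 measured members, 5 had an interval above 1 and 1, miR-196b, below, with a median log2 ratio of 0.40. That is the 99.9th percentile of the random lists, whose abundance match is loose here. Random lists draw members singly, whereas the rise lay mostly in the miR-10 group of near-identical sequences. The median was 0.24 with scaling by all reads and 0.18 without miR-430. The 4 members of the miR-10 group were all higher, with log2 ratios of 0.59 (0.57 to 0.60) for miR-10a-5p (TACCCTGTAGATCCGAATTTGT), 0.38 (0.37 to 0.39) for miR-10b-5p (TACCCTGTAGAACCGAATTTGT), 0.42 (0.41 to 0.44) for miR-10c-5p (TACCCTGTAGATCCGGATTTGT) and 0.69 (0.61 to 0.77) for miR-10d-5p. Together the miR-10 group took 5.59% of control and 7.62% of gata5/6 microRNA reads. The miR-196 members were nearly level, at 0.14 (0.05 to 0.24) for miR-196a and -0.06 (-0.11 to -0.01) for miR-196b, and miR-196b turns positive with median-of-ratios scaling. Scaling by all reads or without miR-430 shifts log2 ratios by -0.16 or -0.22, which turns miR-196a negative. By annotation the miR-10a gene lies in hoxb1b, miR-10c in hoxb3a, copies of miR-10b in hoxd3a and hoxc3a, and miR-196b between hoxb10a and hoxb9a, while miR-10d lies between lnpk and mtx2.

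The let-7 list, microRNAs that accumulate as embryos mature, was also higher in the gata5/6 library. Of 13 measured members, 5 had an interval above 1, 1 below and 7 spanning 1, with a median log2 ratio of 0.42 at the 99.7th percentile, and 0.26 with scaling by all reads or 0.20 without miR-430. Here too random lists draw members singly, whereas the let-7 members are similar in sequence. By annotation, copies of let-7a, miR-100 and miR-125b also share loci. The 5 depend on the scaling. Scaling by all reads shifts log2 ratios by -0.16, more than the lower interval ends of let-7a, let-7g and miR-125b (0.05, 0.13 and 0.08). Their intervals then span 1. Examples were miR-100 at 0.60 (0.40 to 0.79), let-7a at 0.32 (0.05 to 0.60) and let-7g at 0.42 (0.13 to 0.71), whereas let-7h, with 25 and 8 reads, had -1.44 (-2.86 to -0.31). For let-7e the value was 0.12 (-0.38 to 0.63), which turns negative with scaling by all reads or without miR-430. The list held 1161 control and 1429 gata5/6 reads in all.

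The blood list had 3 of 5 measured members with an interval above 1 and the other 2 spanning 1. These 3 were miR-146a at 0.76 (0.63 to 0.90), miR-146b at 0.72 (0.45 to 0.99) and miR-155 at 0.70 (0.38 to 1.02), microRNAs of immune cells and inflammatory signalling rather than of red cells. For miR-150 the value was -0.17 (-0.65 to 0.30) and for miR-142a-5p -0.90 (-2.36 to 0.35). With exact sequences miR-155 had 2.48 and miR-150 -1.20, both outside these intervals. Neither was counted as higher or lower then, so each had under 100 exact reads. The miR-155 value equals that of miR-30a, which rests on 0 control and 2 gata5/6 exact reads. The red-cell microRNAs miR-144 and miR-451 had 1 and 4 reads in each library. The list median was 0.70, at the 99.7th percentile of random lists that draw members singly, whereas miR-146a and miR-146b are close in sequence. With no minimum of reads the median was 0.145. That is the value the scaling gives to equal counts, such as those of miR-144 and miR-451. Reads with motifs of bacterial 16S ribosomal RNA were also higher in the gata5/6 library, at 2797 against 1379. Whether they relate to these microRNAs was not tested.

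The muscle list did not move as a group. Of 4 measured members, the skeletal muscle microRNA miR-206 (TGGAATGTAAGGAAGTGTGTGG) was higher in the gata5/6 library, with 887 and 1275 reads and a log2 ratio of 0.67 (0.54 to 0.79), and 3 had intervals spanning 1. These were miR-133b at -0.05, miR-133c at -0.31 and miR-133a at -0.10; the direction of miR-133a and miR-133b depends on the scaling. The list median was -0.07, at the 52.7th percentile, and it turns positive with median-of-ratios scaling, no minimum of reads or exact sequences. Heart and muscle microRNAs miR-1 and miR-499 had 1 and 4 reads in each library, so no difference was detectable at this depth. Both miR-1 and miR-133a have 2 genes in the annotation, 1 copy of each in mib1 beside gata6 and the other copies between slco4a1 and si:dkeyp-73a2.2.

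The skin and epithelium, p53-responsive and miR-17 to miR-92 lists had negative medians that did not stand apart from abundance-matched lists. In the skin and epithelium list 6 of 8 measured members had an interval below 1 and 2 spanned 1, with a median log2 ratio of -0.24 at the 9.05th percentile. Examples were miR-203a at -0.19 (-0.24 to -0.14), miR-205 at -0.26 (-0.32 to -0.20) and miR-429a at -0.44 (-0.55 to -0.34). The p53-responsive list had a median of -0.39 at the 8.95th percentile, with 2 of 4 members below 1 and 2 spanning it, miR-34a at -0.36 (-0.65 to -0.07) and miR-192 at -0.18 (-0.24 to -0.12) being the 2. The others were miR-194a at -0.41 (-0.99 to 0.14) and miR-34c at -0.47 (-1.88 to 0.82). In the miR-17 to miR-92 list 10 of 15 members lay below 1, 2 above and 3 spanned it, with a median of -0.13 at the 18.4th percentile, with miR-17a at -0.26 (-0.34 to -0.18) and miR-25 at -0.12 (-0.15 to -0.08). The median of all 107 microRNAs was itself -0.10 (quartiles -0.32 and 0.13). Of the 107, 44 had an interval below 1, 24 above and 39 spanning 1, so intervals below 1 were common outside these lists too. The medians of these 3 lists lay inside the central 95% of their random lists.

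The lists for digestive organs, mesenchyme, the nervous system and sensory organs lay inside the range of the random lists, between the 25.7th and 82.3rd percentiles. The liver, pancreas and gut list had 1 of 4 members below 1, miR-192, and 3 spanning it, with a median of -0.02 at the 57.6th percentile. That median turns positive with TMM (0.04) or median-of-ratios scaling (0.08). The islet microRNA miR-375 had 30 reads in each library. Its log2 ratio of 0.15 (-0.63 to 0.92) turns negative with scaling by all reads or without miR-430, and that of miR-216b, 0.27 (-1.04 to 1.59), turns negative with exact sequences. For the mesenchyme list 2 of 4 members lay below 1 and 2 spanned it (median -0.28, 25.7th percentile), miR-143 at -0.31 (-0.52 to -0.11) and miR-140-3p at -0.25 (-0.37 to -0.12) being the lower ones. The others were miR-199-3p at 0.00 (-0.34 to 0.34), whose direction depends on the scaling, and miR-214 at -0.42 (-1.76 to 0.81). The neural list had miR-7b above 1, 3 of 10 members below, among them miR-138 at -0.51 (-0.89 to -0.14), and 6 spanning it (median -0.23, 28.6th percentile). Among the latter were miR-9-5p at 0.22 (-0.01 to 0.46) and miR-128 at 0.14 (-0.03 to 0.30), which turns negative with scaling by all reads, without miR-430 or with exact sequences. The neural median turns positive when only exact sequences are counted, at 0.16, but that is the value the scaling gives to equal counts. Then miR-138 has -1.43, outside its interval. It was not counted as lower there, so it had under 100 exact reads. In the sensory list 1 of 4 members lay above 1, miR-182 at 0.19 (0.13 to 0.25), 1 below, miR-183 at -0.26 (-0.39 to -0.12), and 2 spanned it (median 0.09, 82.3rd percentile). The sensory median turns negative with scaling by all reads (-0.07) or without miR-430 (-0.12), and miR-182 turns negative without miR-430. The spanning members were miR-96 at 0.34 (-0.82 to 1.54) and miR-204 at 0.00 (-0.25 to 0.25), whose direction depends on the scaling. Smooth muscle and endothelium had 1 measured member each, miR-143 and miR-126a-5p, the latter at -0.09 (-0.24 to 0.06) and positive with median-of-ratios scaling.

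**Figure D2:**
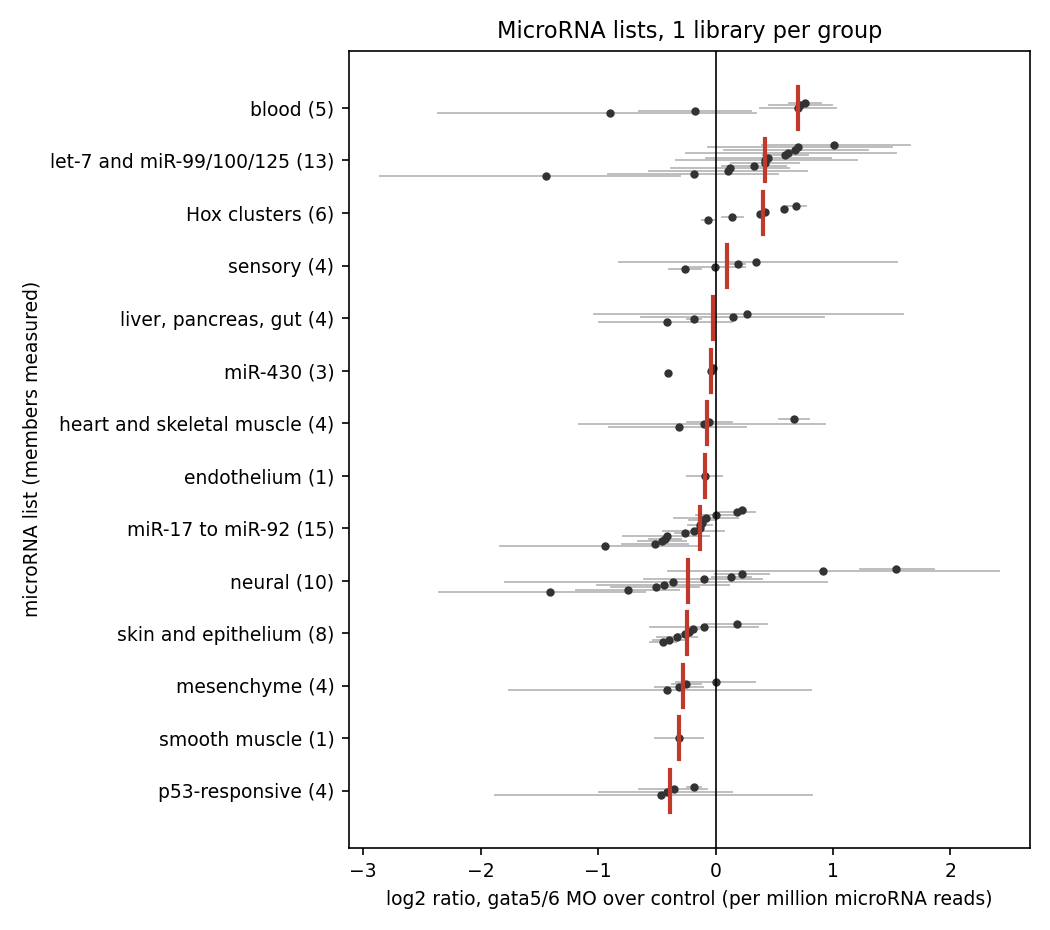
Log2 ratio of the gata5/6 MO to the control library, scaled to microRNA reads, for the measured members of the 14 lists. Each point is 1 microRNA with its 95% counting interval (grey), and the red bar is the list median, which was 0.70 for blood, 0.42 for let-7, 0.40 for the Hox clusters and -0.39 for p53-responsive microRNAs.

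Listed microRNAs took a smaller part of the gata5/6 library. Their share was 58.5% of control reads (58.45% to 58.51%, Clopper-Pearson) and 52.2% of gata5/6 reads (52.21% to 52.27%), a difference of -6.24 percentage points. Reads of 22 to 23 bases made up 62.8% and 58.1% of the libraries, reads of 18 to 21 bases outside the microRNAs 8.11% and 10.2%, and reads of 26 to 30 bases outside the microRNAs, the size range of piRNAs, 16.4% and 18.1%. Of the latter 56.01% in the control and 46.2% in the gata5/6 library began with T, the base most piRNAs start with. Those that began with T made up 9.20% of all control and 8.34% of all gata5/6 reads, a ratio of 0.907 (0.904 to 0.910). Scaled to microRNA reads their log2 ratio was 0.02. Reads with motifs of bacterial 16S ribosomal RNA made up 0.0140% of the control and 0.0281% of the gata5/6 library.

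**Figure D3:**
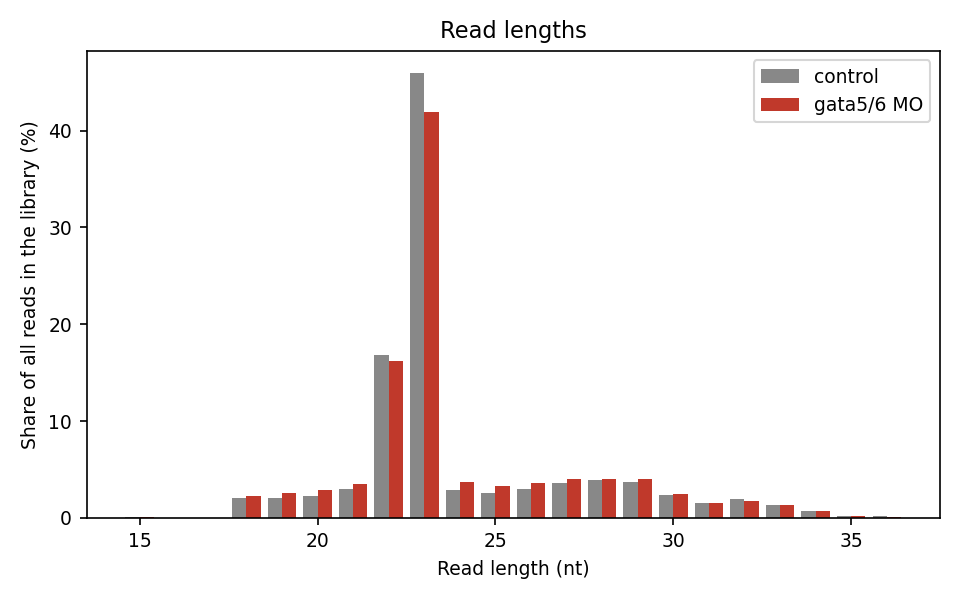
Share of all reads in each library (y axis, percent) by read length (x axis, bases), for the control (grey) and the gata5/6 MO library (red). The peak at 23 bases held 46.0% of control and 41.9% of gata5/6 reads.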

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

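The miR-738 and miR-129-5p tests and the search for bacterial motifs were chosen after the results were seen, and the GC and length tests were written before their outcome was known.

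Reads with motifs of bacterial 16S ribosomal RNA were present outside the microRNA reads and were higher in the gata5/6 library than in the control. They were not checked against zebrafish ribosomal RNA, so a bacterial origin was not tested. Reads with 5 conserved motifs of bacterial 16S rRNA numbered 1379 in the control and 2797 in the gata5/6 library, a ratio of 2.003 per read sequenced (1.88 to 2.14, counting error only). The motifs had ratios from 1.17 to 2.34, and the interval of 1 of the 5 reached 1 (0.982 to 1.39). They made up 0.0140% and 0.0281% of all reads.

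The lower miR-738 signal may come from fragments of a longer RNA. Of 1221 reads with the core of its sequence, 1.72% began at the mature 5′ end, whereas the other microRNAs with at least 100 reads had a median of 99.2% and a lowest share of 38.2%. That measure leaves out most miR-722 reads. Among assigned reads the shares at the 5′ end were 4.04% and 2.56% for miR-738 and 10.8% and 7.04% for miR-722 in the control and gata5/6 libraries, so a low share is not particular to miR-738. The core reads of miR-738 had a median length of 27 bases and 17 start positions, and numbered 1062 in the control and 159 in the gata5/6 library. Which RNA they derive from was not tested, and an effect of the MOs on that RNA stays open, untested with 1 library per group.

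The authors' deposited table lists miR-129-5p at 19 control and 44 gata5/6 reads, while assigned reads were nearly equal, at 18 and 17. A candidate explanation is reads of another RNA that match with mismatches. Reads with 1 or 2 mismatches numbered 61 and 101, with a log2 ratio of 0.87, which goes the authors' way. Nearly all of them had 2 mismatches, at 59 and 100, and those with 1 numbered 2 and 1. Reads with at most 1 mismatch therefore do not reach the authors' 44 in the gata5/6 library. Added to the 17 matching reads of each library, the reads with 1 or 2 mismatches exceed the authors' counts. The test thus left reads with 2 mismatches undecided, and the authors' assignment rule is not given in the sources used here.

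The Hox-cluster and let-7 lists were higher in the gata5/6 library. The rank trend with GC content over 139 microRNAs was weak (Spearman's rho 0.09, across microRNAs, which are not independent replicates). Removing a linear GC trend left at least 99.3% of each list's excess over the median of all. The trend with mature length was as weak (rho 0.08), and removing it left at least 102.3%. The weakness of the GC trend argues against a linear GC trend as the cause. The share left adds nothing to that, since removing so weak a trend could hardly lower it. All measured members of both lists are 22 bases long, so removing a length trend moved them alike and that test could not decide. Against lists matched on GC the Hox and let-7 medians lay at the 98.9th and 99.97th percentiles, and on length at the 98.04th and 99.7th. These random lists also drew members singly. An effect of the MOs, a difference in developmental stage between the pools, and differences between library preparations stay open, and could not be tested with 1 library per group.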

How the results depend on the processing

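The alternative without miR-738 and the one without miR-206 were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The same 2 higher and 2 lower microRNAs were counted under TMM, median-of-ratios, all-read and without-miR-430 scaling, with ambiguous reads split and with a pseudocount of 1; scaling without miR-430 added miR-181a-3p to the lower ones. Counts depended on the limits themselves: with no minimum of reads 5 were higher and 5 lower, with a minimum of 20 reads 4 and 5, at 1.5-fold 10 and 4, and at 4-fold 0 and 1. Counting exact mature sequences left 2 higher and 0 lower, since miR-722 had 0 such reads and miR-738 had 2, under the minimum of 100, and 3 of the authors' 8 in place of 7, which was 6 with all-read or without-miR-430 scaling; the difference in microRNA share became -5.77 points. Without miR-738, 1 was lower. The miR-430 median (-0.04) was 0.020 with TMM, 0.060 with median-of-ratios, -0.20 with all reads, -0.25 without miR-430 and -0.048 with exact sequences. The muscle median was -0.10 without miR-206. Scaling moved the median of the 107 microRNAs by 0.06 with TMM, 0.10 with median-of-ratios, -0.16 with all reads and -0.22 without miR-430. Of the 54 named microRNAs 15, with log2 ratios from -0.10 to 0.27, changed sign under some alternative. The 4 counted ones did not, but miR-722 has no value with exact sequences and that of miR-738 rests on 2 reads. The Hox median (0.40) ranged from 0.18 without miR-430 to 0.52 with exact sequences, and the let-7 median (0.42) from 0.20 without miR-430 to 0.52 with median-of-ratios. The neural median was 0.16 with exact sequences, the value that equal counts have under that scaling. Depth limits microRNAs with few reads, such as miR-1 and miR-144.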

Other observations

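The values given here were chosen after they were seen. The arms of 2 hairpins differed in their shift between libraries. From the miR-181a hairpins, the 3p arm (ACCATCGACCGTTGATTGTACC) had 7916 control and 4039 gata5/6 reads and a log2 ratio of -0.83 (-0.88 to -0.77), while the 5p arm (AACATTCAACGCTGTCGGTGAGT) had -0.04 (-0.08 to 0.01). The difference of 3p minus 5p was -0.79 (-0.86 to -0.72). For miR-210 both arms were higher in the gata5/6 library, 3p at 0.82 (0.59 to 1.06) and 5p at 1.44 (1.22 to 1.66), with a difference of -0.62 (-0.93 to -0.30). The intervals of the other 3 hairpins with at least 100 reads of each arm, miR-126a, miR-140 and miR-199, spanned 0. The annotation has several genes for miR-181a, which were not separated. Also higher in the gata5/6 library was miR-184, at 0.50 (0.43 to 0.56). The liver microRNA miR-122 had 3 control and 14 gata5/6 reads.

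The 4 tRNA 5′ fragments reported here were less abundant in the gata5/6 library when scaled to all reads. Together they took 1.62% of control and 1.05% of gata5/6 reads. The tRNA-Gly-GCC fragment (GCATTGGTGGTTCAGTGGTAGAATTCTC) had a ratio of 0.530 (0.525 to 0.536) per read sequenced. Those of tRNA-Val, tRNA-His and tRNA-Lys-CTT were closer to equal, at 0.832, 0.847 and 0.924. Scaled to microRNA reads the tRNA-Lys-CTT fragment turns slightly higher, at a log2 ratio of 0.05, and the others stay lower. These values are counting results of 1 library per group.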
